A study of Caenorhabditis elegans with 16 samples.

How the data were processed

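RNA levels were measured in adult wild-type N2 Caenorhabditis elegans, a nematode, by hybridising Cy3-labelled RNA of whole bodies to Agilent gene expression arrays. Each of the 16 samples went to its own array. Per the labels, the adults were kept in liquid medium with 25 µM FUdR, a compound that blocks the production of progeny, and were exposed for 24 h to water or to a compound: for arsenic, NaAsO2 at 10 µg/ml and DMA at 200 µg/ml, and for mercury, HgCl2 at 2 µg/ml and meHgCl at 0.5 µg/ml. The labels do not spell out DMA and do not say whether the replicates were separate cultures, so the p-values measure the spread between these samples. The 4 slides held 4 arrays each, and each slide was 1 scan, so slide and scan cannot be told apart.

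Per the file headers, Agilent Feature Extraction turned each scan into spot intensities with protocol GE1_1105_Oct12. The submitters' processing notes name version 10.7 of that software, and the file headers name version 11.5.1.1. The processed signal is, per the file headers, an intensity on a linear scale from which background was subtracted and which was corrected for trends across the array, with a small positive value in place of dim spots. It was not normalised between arrays. The median spot and background intensities, per the file headers, carry no such correction, and the quality marks of each spot are 0 or 1. The value table that the authors deposited holds intensities on a linear scale. Its values were the processed signal divided by 1 constant per array, between 0.923 and 1.758, and were not centred per gene. This was tested on the values, because the labels do not state the step. The 75th percentile of the table over all spots was 999.6 to 1000.0 per array, which is nearly the scaling used here.

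From there, control spots were left out, which kept 43803 spots per array. Spots marked as non-uniform or as outliers of their replicate spots were set missing, which was 1 to 52 spots per array. The processed signal was taken to log2, and the 75th percentile of the non-control probes of the array was subtracted. Spots of the same probe were averaged. A probe was tested if it was well above background on every array of at least 1 group, which held for 31711 probes. Gene names came from the array annotation and were updated to current symbols. A gene was represented by the tested probe with the highest mean over all 16 arrays, which left 16096 of 20062 genes. Normalised levels below are log2 values relative to the array's own 75th percentile. No spot was saturated, and 68.5% to 76.6% of the spots of an array were well above background. For arrays, their number limits the precision: 4 with water and 3 in each other group. Genes that belong to families with near-identical members, such as nspa, gst, clec, fbxb and hsp-16, may share signal between members, since probe sequences were not used here.

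Groups came from the labels. Limma 3.58.1 in R 4.3.3 fitted 1 coefficient per group to all 16 arrays, with moderated variances (lmFit and eBayes), and the contrasts were each compound against water, NaAsO2 against DMA and HgCl2 against meHgCl. P-values were adjusted by Benjamini and Hochberg over the genes of a comparison, with a threshold of 0.05, and all p-values are two-sided unless another side is named. These choices, the gene lists, the rule for the genes to name and most alternatives were fixed before the data were examined. A fold change against a group in which a probe was not well above background on any array is given as a lower bound, computed with each such array at its own value or, if that is higher, at the lowest level called well above background on that array.

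The labels give the groups shared replicate numbers 2, 3 and 5, and water also a number 4, without saying what the number marks. The correlation across genes of the deviations from the group mean was 0.221 to 0.669 between a treated array and the water array of the same number. It was 0.471 to 0.810 between the compared forms. Since every pair lay above 0.1, the numbers were read as pairing the samples, as a hint from the data. Water 4, the only array of its number, reached 0.241 with meHgCl 2, so that cut alone does not separate pairs by number. For 15 of 16 arrays, the array in another group with the most similar deviations had the same number. The fit with the number as a fixed block is therefore given beside a result wherever it changed a call or moved a count by more than 1.5 times. The residual standard deviation was 0.38 (log2) without the block and 0.24 with it.

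Genes were named in each comparison by a rule. It took the 8 largest rises and the 8 largest falls (5 and 5 between forms, or all where fewer than 16 qualified) among genes past the threshold whose groups did not overlap and whose probe was well above background on every array of the higher group. Where no gene passed, it took the 4 smallest p-values. It added 12 stress genes in each comparison with water, whatever their result, and for each gene list described up to 4 members past the threshold or up to 2 with the smallest p. One of the 12, gst-4, had no matching probe and was not analysed here. Genes outside the rule are said to have been chosen after their values were seen.

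There were 35 lists of genes, of which those with a result below are described and the rest are given as counts. Lists were tested with limma's camera, which asks whether the members of a list differ from all other genes, with a preset correlation of 0.01 between genes, and again with an estimated correlation. Fry, which asks whether the members move one way on balance, was the other alternative. The 41 genes with a missing value were left out of these tests. Members past the threshold are counted over all genes and, where said, adjusted over the list alone. Gene families defined by their symbol were tested afterwards with a one-sided Fisher's exact test in scipy 1.17.1, against the 16096 genes tested. Positions are those of the genome build WBcel235.

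The procedure was tested on simulated data, in which 100 genes changed by 1 and 100 by 2 (log2). The simulated arrays held the number effects of the blocked fit, added alike to all groups, and independent noise. Without the block it recovered 26% to 33% of the former and 69% to 89% of the latter, and with the block 64% to 69% and 93% to 100%. Since the number effects were simulated as the blocked fit models them, the gain with the block was built in. Of the unchanged genes, 0 to 1 were called without the block and 6 to 15 with it. Comparisons that share the water arrays were set beside a simulation of unchanged groups and beside values from water split into 2 and 2 arrays. The alternatives were another background correction (normexp, offset 50, on the median intensities, which also leaves out the correction for trends), quantile normalisation, scaling on the median, the authors' value table, other probe filters, the mean of a gene's probes, kept outlier spots, fits of only the groups compared, the replicate block, the slide as a fixed or random block, robust moderation with a trend, array weights, and each array left out in turn. Fits without the arrays numbered 2, blocked fits with arrays left out and tests of all probes, named or not, were added after seeing the data, as was the count of genes that rose with both forms of arsenic with water split. Tables and plots were made with Python 3.11.15, pandas 2.3.3 and matplotlib 3.10.9.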

Results

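Gene expression was measured in whole adult N2 worms, the C. elegans reference strain, after 24 h with water or 1 of 4 metal compounds, an inorganic and an organic form of arsenic and of mercury. There were 4 arrays for water and 3 for each compound. For arsenic these were NaAsO2 (sodium arsenite) at 10 µg/ml and DMA, which the labels do not spell out, at 200 µg/ml. For mercury they were HgCl2 (mercuric chloride) at 2 µg/ml and meHgCl (methylmercury chloride) at 0.5 µg/ml. The doses of the forms differed, so a difference between forms is also a difference between doses. Each array held 43803 non-control spots, of which 30006 to 33549 were well above background. The 75th percentile of the processed signal ranged from 963.7 (DMA 5) to 1845 (DMA 2). Replicates of a group correlated at 0.954 to 0.992 across genes, which are not independent replicates. The first principal component held 49.1% of the variance and separated the arrays numbered 2 of all groups from the rest, and the second held 15.3%. Changes below are log2 fold changes ± standard error (SE), with n = 3 treated and n = 4 water arrays. Water 4 is the only array of its number. With the replicate block the contrasts with water therefore rest on the water arrays numbered 2, 3 and 5.

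Sodium arsenite against water asks which genes respond to the inorganic form of arsenic. Glutathione S-transferases, which attach glutathione to reactive compounds, rose: gst-30 by 2.41 ± 0.23, or 5.30-fold (adjusted p = 0.000165), gst-12 by 1.95 ± 0.18 (adjusted p = 0.000165), gst-16 by 2.53 ± 0.31 (adjusted p = 0.00212) and gst-25 by 2.79 ± 0.31 (adjusted p = 0.000818). The gene nit-1, which encodes a nitrilase-like protein, rose by 1.87 ± 0.25 (adjusted p = 0.00489), from a normalised level of 2.00 ± 0.30 (SD, n = 4) to 3.88 ± 0.33 (SD, n = 3). The nematode-specific peptide genes nspa-8, nspa-1 and nspa-5 rose by 5.09 ± 0.47, 3.42 ± 0.51 and 3.25 ± 0.48. The C-type lectin genes clec-3, clec-2 and clec-143 rose by 3.41 ± 0.40, 2.84 ± 0.39 and 1.47 ± 0.24, and F55G11.2 and dod-17 rose by 3.39 ± 0.28 and 2.69 ± 0.29. In each of these 13 genes, all 3 NaAsO2 arrays lay above all 4 water arrays, which the naming rule required of the 8 largest rises. Of all genes tested, 4.21% did not overlap between these groups in either direction, against 5.71% by chance.

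In all, limma called 16 genes higher and 0 lower among 16096 tested, all at least 2-fold. At an unadjusted p under 0.05 there were 400 genes (2.49%), below the 5% expected without any change, and 3592 with the replicate block. Without the block, differences between replicate numbers stay in the residual. A share under 5% therefore does not show that changes were absent, here or in the comparisons below. The remaining 3 genes, dod-24 (2.42), F01D5.3 (1.78) and asp-14 (also higher with DMA, by 1.19), were outside the naming rule and chosen after their values were seen. With the replicate block, 33 genes were higher and 42 lower, 75 in all and 16 of them shared. Without Water 5 the blocked count was 1054, and it was 35 without Water 3, 49 without NaAsO2 2 and 31 without NaAsO2 3 or NaAsO2 5. Without the block, 9 genes passed without NaAsO2 3. In its absence nspa-1, nspa-5, clec-2, nit-1 and clec-143 did not pass (adjusted p = 0.12, 0.11, 0.060, 0.054 and 0.23). Without NaAsO2 5, nspa-1, nspa-5, nit-1 and clec-143 did not pass (adjusted p = 0.12, 0.12, 0.056 and 0.19). The call of clec-143 was also lost without Water 2, Water 3 or Water 4 (adjusted p = 0.062, 0.089 and 0.070). With normexp background correction gst-25, whose signal was well above background on 2 of 4 water arrays, did not pass (adjusted p = 0.18). In a fit of the 2 groups alone clec-143 did not pass (0.17).

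The 3 genes F55G11.2, dod-17 and dod-24 lie on chromosome IV between 12940106 and 12978343 (WBcel235). The gene gst-12 (F37B1.2) lies on chromosome II at 13616682 to 13618061, and gst-30 (ZK546.11) at 4933883 to 4935054 on the same chromosome. Clec-3 lies on chromosome II at 3017468 to 3019907, gst-25 on chromosome I at 1451081 to 1453070, nit-1 (ZK1058.6) on chromosome III at 3922207 to 3923873 and nspa-8 (W06A7.5) on chromosome V at 14826948 to 14827052. All are annotated as protein-coding.

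Among 17 phase II targets of SKN-1, the transcription factor of the oxidative stress response, 3 rose and 0 fell with NaAsO2, or 9 rose adjusted over the list alone. Their median change was 0.69 (camera adjusted p = 4.56e-22, and adjusted p = 0.0537 with an estimated correlation). Of 46 glutathione S-transferases, 4 rose, or 7 rose and 1 fell adjusted over the list alone. Their median was 0.03 and their mean 0.34 (adjusted p = 2.64e-06, and 0.837 with an estimated correlation). The median of the glutathione S-transferases was 0.20 without NaAsO2 2, 0.01 without Water 3, 0.05 without Water 4 and 0.08 without Water 5. With the block, 6 glutathione S-transferases rose and 1 fell. Gcs-1, the glutathione synthesis enzyme glutamate-cysteine ligase, had a change of 0.83 ± 0.17 (adjusted p = 0.135, 0.0474 with the slide as a random block and 0.00075 with array weights). None of the 9 metallothioneins and cadmium-responsive genes passed (0 by limma, 0 adjusted over the list alone, median -0.30, adjusted p = 0.294). Mtl-1 and mtl-2, the metal-binding metallothioneins, had changes of -0.32 ± 0.55 and -0.33 ± 0.23, cdr-1 0.06 ± 0.19, cdr-7 -0.50 ± 0.31 and numr-1 -0.47 ± 0.34.

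Other stress genes did not pass with NaAsO2. The heat shock genes hsp-16.2, hsp-70, hsp-16.48 and hsp-16.41 had changes of -0.37 ± 0.37, 0.10 ± 0.84, -0.60 ± 0.23 and -0.51 ± 0.21. The median of 17 heat shock proteins was -0.10 (adjusted p = 0.290), and without NaAsO2 2 it was -0.22 (adjusted p = 0.00449). The chaperones hsp-4 of the endoplasmic reticulum and hsp-6 of mitochondria had changes of 0.07 ± 0.43 and 0.34 ± 0.48. The superoxide dismutase gene sod-3 and the yolk protein gene vit-2 had changes of -0.06 ± 0.63 and -0.22 ± 0.21. The median of 33 proteasome subunits was 0.08 (adjusted p = 0.00549, and 0.837 with an estimated correlation), with rpn-1 at 0.51 ± 0.27 and rpn-2 at 0.45 ± 0.25. That call was lost without Water 2 (adjusted p = 0.0861) or NaAsO2 3 (adjusted p = 0.155). The median of the subunits was 0.03 without Water 2, 0.14 without Water 4 and 0.17 without NaAsO2 5.

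Among immune genes with NaAsO2, 3 of 166 C-type lectins rose, or 4 adjusted over the list alone, while the list's median was -0.13 and its mean -0.05 (adjusted p = 0.766). Of 69 innate immune effectors none passed over all genes and 1 rose adjusted over the list alone. Their median was -0.32 (adjusted p = 0.000319, 0.837 with an estimated correlation, and 0.103 without NaAsO2 2), and with the block 3 fell. The members with the smallest p were irg-5 (0.93 ± 0.19, adjusted p = 0.135, 0.014 without Water 2 and 0.0026 with array weights) and irg-3 (0.49 ± 0.16). The 34 intracellular pathogen response genes had a median of -0.32 (adjusted p = 0.00639, and 0.837 with an estimated correlation), with pals-25 at -0.45 ± 0.20 and pals-1 at -0.63 ± 0.35. That call was lost without NaAsO2 2 (adjusted p = 0.711), NaAsO2 3 (0.116) or Water 4 (0.193). The median of 27 germline and oocyte markers was 0.57 (adjusted p = 3.99e-08, and 0.837 with an estimated correlation), with glp-1 at 0.75 ± 0.42 and oma-2 at 0.66 ± 0.40, and by replicate number it was 1.27, 1.05 and -0.16. The median of 39 sperm markers was -0.05 (adjusted p = 0.487, and 0.00291 with the block at a median of -0.28). Without Water 2 it was 0.27 (adjusted p = 0.00779), without NaAsO2 2 -0.26 (adjusted p = 9.54e-05) and without Water 4 -0.28 (adjusted p = 0.00149). Left-out arrays moved the medians of called lists. Without NaAsO2 2 those of the innate immune effectors, the intracellular pathogen response and the germline markers were -0.14, -0.12 and 0.36. Without NaAsO2 5 the last 2 were -0.72 and 0.87, without Water 3 the first was -0.22, and without Water 2 the second was -0.49. In all, 10 of 35 lists passed with the preset correlation and 0 with an estimated one, where camera gave 1 list an unadjusted p under 0.05.

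DMA against water asks which genes respond to the organic arsenic compound. The detoxification gene ugt-34, a UDP-glucuronosyltransferase, rose at least 35.9-fold (adjusted p = 1.57e-06), from a signal that was not well above background on any water array. C15B12.8 rose by 4.67 ± 0.29, or 25.4-fold (adjusted p = 1.57e-06). The glutathione S-transferases gst-12, gst-30, gst-25 and gst-16 rose by 2.56 ± 0.18, 2.91 ± 0.23, 3.38 ± 0.31 and 2.76 ± 0.31 (adjusted p = 6.59e-06, 1.76e-05, 9.03e-05 and 0.000634). The cadmium-responsive gene cdr-1 rose by 2.31 ± 0.19 (adjusted p = 2.37e-05) and the cytochrome P450 gene cyp-35D1 by 2.48 ± 0.25 (adjusted p = 0.000182). The largest falls were those of the C-type lectin genes clec-70 (-3.11 ± 0.59, adjusted p = 0.0375) and clec-169 (-2.69 ± 0.46, adjusted p = 0.0238) and of Y38E10A.9 (-2.29 ± 0.29, adjusted p = 0.00206).

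Further genes that rose with DMA were nspa-8 (4.45 ± 0.47), nspa-1 (3.13 ± 0.51), nspa-5 (2.90 ± 0.48) and gst-37, whose rise was at least 3.32-fold from a signal not well above background on any water array. Clec-3 (2.64 ± 0.40), clec-2 (1.92 ± 0.39), the P450 gene cyp-14A4 (2.19 ± 0.42), the short-chain dehydrogenase gene dhs-8 (2.10 ± 0.24), gst-14 (2.00 ± 0.31) and the infection response gene irg-5 (1.45 ± 0.19) rose as well. Further falls were those of fbxb-66 (-1.94 ± 0.38), C17H12.8 (-1.91 ± 0.31), W10D9.1 (-1.84 ± 0.33), clec-168 (-1.82 ± 0.25), F07C4.6 (-1.79 ± 0.28), cyp-34A1 (2.47-fold lower, adjusted p = 0.0395) and the nuclear hormone receptor gene nhr-171 (-1.25 ± 0.25). The plot of single arrays shows 8 of the genes named in the comparisons.

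**Figure D1:**
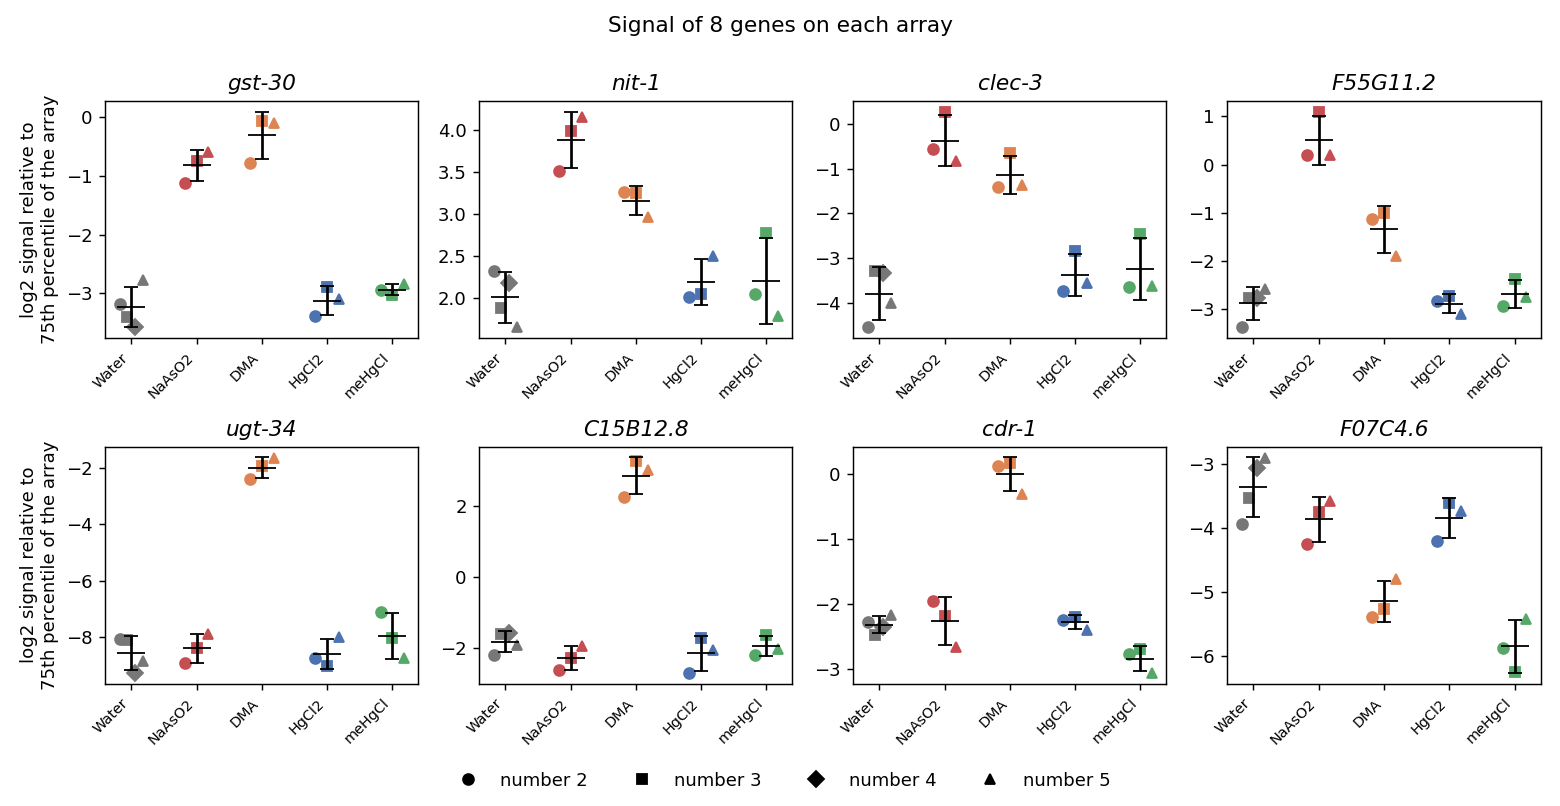
Normalised log2 level (relative to the array's 75th percentile) of 8 genes in the 5 groups, with each point an array, its marker the replicate number, and the bar the mean ± SD (n = 4 for water, n = 3 for the others). The levels of gst-30 rose from -3.23 with water to -0.82 with NaAsO2 and -0.32 with DMA, while ugt-34 and C15B12.8 stood apart with DMA, at -2.003 and 2.853.

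In all, limma called 71 genes with DMA, 31 higher and 40 lower, 64 of them at least 2-fold. At an unadjusted p under 0.05 there were 1446 genes (8.98%, against 5% expected without any change), and 2695 with the replicate block. Of the 43 outside the naming rule for this comparison, 13 rose by 0.65 to 2.85 and 30 fell, with changes from -1.71 to -0.89. With the replicate block the count was 663, 116 higher and 547 lower, and all 71 were among them. With normexp, which changes the background step and the intensity used together, 28 genes were higher and 7 lower, and 33 of the 71 were called, and which of these changes moved the counts was not tested. The normexp changes of F07C4.6 (-0.37), W10D9.1 (-0.00), clec-169 (-1.35), clec-70 (-2.07), fbxb-66 (-1.78), nhr-171 (-0.37), cyp-34A1 (-0.61), clec-2 (1.39) and gst-37 did not pass (adjusted p = 0.69, 1, 0.11, 0.21, 0.077, 0.61, 0.54, 0.11 and 0.27), and that of clec-168 was 0.13. Scaling on the median gave 35 higher and 24 lower and shifted the median change of all genes by 0.126, and normexp shifted it by 0.104. Single arrays moved the count to 187 without DMA 5, 16 without DMA 3, 21 without Water 5, 26 without Water 3, 32 without DMA 2 and 41 without Water 4. The blocked count was 195 without Water 3, 181 without DMA 3 and 335 without DMA 2.

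Several DMA calls were lost when 1 array was left out. Without DMA 3, those lost were nspa-1, nspa-5, gst-14, clec-3, clec-2, cyp-14A4, clec-70, clec-169, fbxb-66, C17H12.8, W10D9.1, clec-168, F07C4.6, cyp-34A1 and nhr-171, with adjusted p from 0.058 (clec-168) to 0.34 (clec-2). Without DMA 2, clec-169, fbxb-66, C17H12.8, W10D9.1, F07C4.6, cyp-14A4, cyp-34A1, clec-2 and nhr-171 were lost (adjusted p from 0.051 for C17H12.8 to 0.16 for nhr-171). Clec-70, at -2.62 (0.074), and cyp-14A4 (0.053) were also lost without DMA 5. Without Water 3 the same held for nspa-5, clec-70, clec-169, fbxb-66, W10D9.1, cyp-14A4, cyp-34A1, clec-2 and nhr-171 (up to 0.12 for nhr-171). Without Water 5 it held for nspa-1, nspa-5, clec-70, clec-169, fbxb-66, C17H12.8, W10D9.1, F07C4.6, cyp-34A1, clec-2 and nhr-171 (up to 0.15 for nhr-171). Without Water 4 it held for clec-70, clec-169, fbxb-66, W10D9.1, cyp-14A4, cyp-34A1, clec-2 and nhr-171, and without Water 2 for fbxb-66, cyp-14A4, cyp-34A1, clec-2 and nhr-171 (up to 0.10 for fbxb-66 in the former and 0.080 for clec-2 in the latter). In a fit of the 2 groups alone gst-37, nspa-1, nspa-5, clec-70, clec-169, fbxb-66, W10D9.1, clec-168, F07C4.6, cyp-14A4, cyp-34A1, irg-5, clec-3, clec-2 and nhr-171 did not pass (adjusted p from 0.0501 for gst-37 and clec-3 to 0.14 for clec-70 and fbxb-66). With no filter on dim probes fbxb-66, cyp-34A1, clec-2 and nhr-171 did not pass (up to 0.067), with the mean of a gene's probes cyp-34A1, clec-2 and nhr-171 (up to 0.057) and with robust moderation with a trend clec-2 and nhr-171 (0.054 and 0.058). With quantile normalisation clec-70, cyp-34A1 and nhr-171 did not pass (0.051, 0.058 and 0.055), and with median scaling cyp-34A1 and nhr-171 (0.058 and 0.057).

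The gene ugt-34 (F29F11.2) lies on chromosome V at 10654415 to 10656978, C15B12.8 on chromosome X at 6474264 to 6476645 and cdr-1 on chromosome V at 15921309 to 15922820. Cyp-35D1 lies on chromosome V at 16069238 to 16071318, dhs-8 on chromosome II at 14498026 to 14499755, clec-70 on chromosome IV at 3932708 to 3936307, irg-5 on chromosome V at 13737010 to 13738474 and gst-37 on chromosome V at 1921621 to 1922381 (WBcel235, all protein-coding).

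With DMA, 4 of 17 SKN-1 phase II targets rose and 0 fell, or 13 rose adjusted over the list alone, at a median of 0.96 (camera adjusted p = 4.10e-26, and adjusted p = 0.0290 with an estimated correlation). With the block 11 rose. By replicate number 2, 3 and 5 the list's median was 0.38, 1.14 and 1.31 with DMA, and 0.26, 0.75 and 0.85 with NaAsO2. Gcs-1 had a change of 0.67 ± 0.17 (adjusted p = 0.10, 0.0423 with the block, 0.0449 with the slide as a random block and 0.0020 with array weights). Of 46 glutathione S-transferases 7 rose, or 17 rose and 1 fell adjusted over the list alone, at a median of 0.32 (adjusted p = 3.69e-16, and 0.207 with an estimated correlation), and with the block 16 rose and 2 fell. Of 70 cytochromes P450 2 rose and 1 fell, the same adjusted over the list alone, at a median of 0.10 (adjusted p = 0.494, and 0.00633 without DMA 2, at a median of 0.36), and with the block 2 rose and 3 fell. Of 64 UDP-glucuronosyltransferases 1 rose, likewise adjusted over the list alone, and 4 rose and 1 fell with the block. Their median was 0.13 (adjusted p = 0.000722, 0.969 with an estimated correlation, and 0.184 with normexp), and 0.00 without Water 4 or with the block, 0.22 without Water 2 and 0.30 without DMA 2. Of 9 metallothioneins and cadmium-responsive genes only cdr-1 rose, also adjusted over the list alone. That list's median was 0.17 (adjusted p = 0.0419, 0.688 with an estimated correlation and 0.181 with the block). Its call was also lost under quantile normalisation (adjusted p = 0.0962), median scaling (0.0692), normexp (0.425), no filter on dim probes (0.0764) and the slide as a fixed block (0.0564), and without DMA 3 (0.0619), DMA 5 (0.238) or Water 4 (0.132). Its median was 0.11 without DMA 3, 0.06 without DMA 5, 0.08 without Water 4 and 0.29 without DMA 2. That of the glutathione S-transferases was 0.52 without DMA 2.

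Mtl-1, mtl-2 and numr-1 had changes of 0.21 ± 0.55, 0.17 ± 0.23 and -0.72 ± 0.34 with DMA. Hsp-16.2, hsp-70, hsp-4 and hsp-6 had changes of -0.21 ± 0.37, -0.23 ± 0.84, -0.23 ± 0.43 and 0.34 ± 0.48, and hsp-16.41 and hsp-16.48 of -0.34 ± 0.21 and -0.36 ± 0.23. Sod-3 and vit-2 had changes of 0.64 ± 0.63 and -0.04 ± 0.21. The median of 17 heat shock proteins was -0.20 (adjusted p = 0.582, and 0.0096 with normexp at a median of -0.08).

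Among immune genes with DMA, 2 of 166 C-type lectins rose and 3 fell, or 2 and 12 adjusted over the list alone, and with the block 3 rose and 23 fell. Their median of -0.38 (adjusted p = 1.17e-06, and adjusted p = 0.0465 with an estimated correlation) turned to 0.13 with normexp (adjusted p = 0.184). Of 69 innate immune effectors 1 rose (irg-5) and 1 fell (C17H12.8), or 1 and 7 adjusted over the list alone, and with the block 1 rose and 13 fell. Their median was -0.09 and their mean -0.30 (adjusted p = 0.0106, 0.969 with an estimated correlation, 0.646 without DMA 2, 0.191 without Water 3, and 0.0564 with the slide as a fixed block at a median of -0.06). None of the 34 intracellular pathogen response genes passed. Their median was -0.42 (adjusted p = 0.00456, and 0.969 with an estimated correlation), with pals-3 at -1.38 ± 0.59 and pals-28 at -1.71 ± 0.74, and the call was lost without DMA 2 (0.616) or Water 4 (0.0609). The median of the innate immune effectors was -0.01 without DMA 2, -0.04 without Water 3, -0.22 without Water 2, -0.21 without DMA 3 and -0.25 without DMA 5. That of the intracellular pathogen response was -0.09 without DMA 2, -0.63 without Water 2 and -0.88 without DMA 5. The median of 39 sperm markers was 0.41 (adjusted p = 1.17e-06, and 0.969 with an estimated correlation), with ssp-34 at 0.69 ± 0.33 and msp-45 at 0.60 ± 0.35, and it was 0.15 without Water 4 or with the block and 0.71 without Water 2. The median of 27 germline and oocyte markers was 0.11 (adjusted p = 0.168, and 0.00818 with the block), with glp-1 at 0.40 ± 0.42 and cpg-2 at 0.22 ± 0.26. By number it was 1.21, 0.15 and -0.44. The germline list passed without DMA 3 (adjusted p = 0.00683), DMA 5 (0.00162) or Water 4 (0.0159). In all, 9 of 35 lists passed with the preset correlation and 2 with an estimated one, the SKN-1 targets and the C-type lectins.

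**Figure D2:**
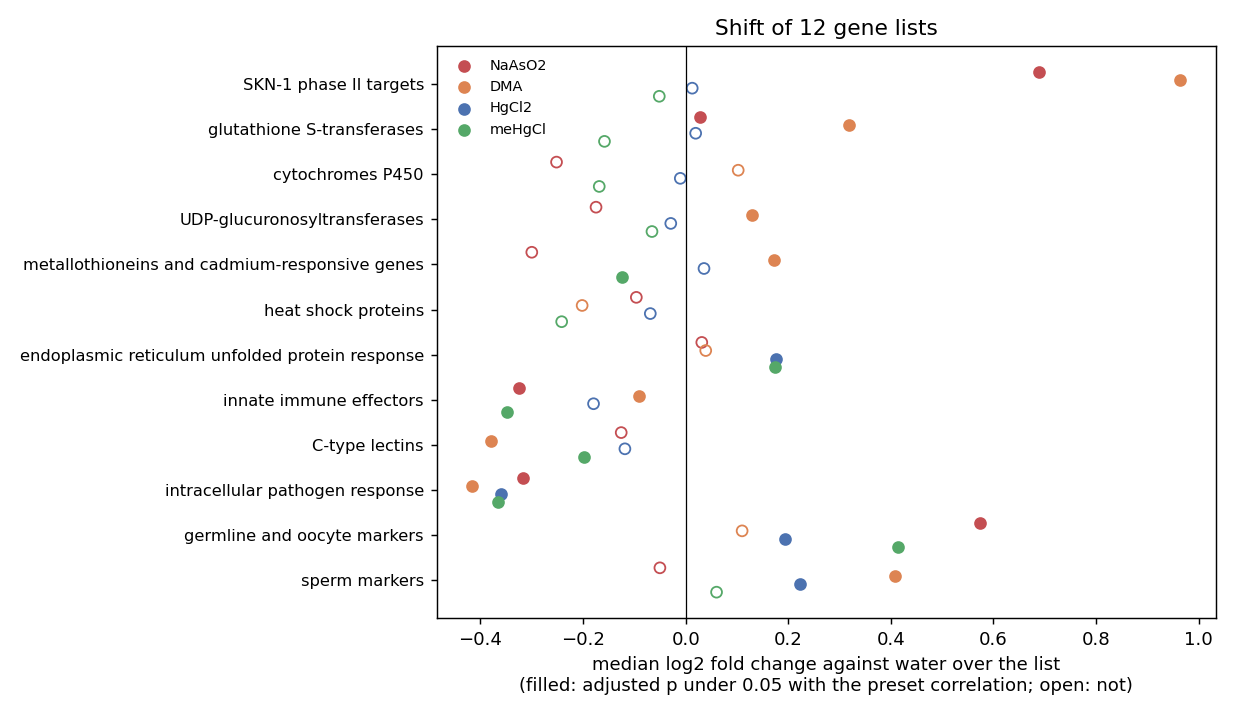
Median log2 fold change of the members of 12 gene lists in the comparisons, with a filled point where camera's adjusted p was under 0.05 with the preset correlation. The medians of the SKN-1 targets were 0.69 with NaAsO2 and 0.96 with DMA against 0.01 and -0.05 with the mercury compounds, and that of the C-type lectins with DMA was -0.38, or 0.13 with normexp.

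HgCl2 against water asks which genes respond to inorganic mercury. No gene passed (0 by limma). At an unadjusted p under 0.05 there were 556 genes (3.45%), below the 5% expected without any change. Of all genes tested, 5.77% did not overlap between these groups in either direction, against 5.71% by chance. The 4 genes with the smallest p were grd-7 (at least 1.104-fold lower, adjusted p = 0.222), gadr-1 (-1.39 ± 0.27), ncbp-2 (-0.94 ± 0.21) and F58D2.3 (-1.58 ± 0.36), with all 3 HgCl2 arrays below all 4 water arrays in the last 3. With array weights these 4 genes passed (adjusted p = 0.0021, 0.0021, 0.036 and 0.037), and grd-7 passed with the slide as a fixed or random block (0.046 and 0.025). Grd-7, on chromosome X at 7267870 to 7269479, was not well above background on any HgCl2 array, and its direction turned with normexp. F58D2.3 on HgCl2 2 and HgCl2 3, and gadr-1 on HgCl2 3, lay below the lowest level called well above background on that array. The sizes given for F58D2.3 and gadr-1 are therefore uncertain. Mtl-1 and mtl-2 had changes of -0.03 ± 0.55 and 0.24 ± 0.23, cdr-1 and numr-1 of 0.04 ± 0.19 and -0.38 ± 0.34. Hsp-16.2, hsp-70, hsp-4 and hsp-6 had changes of -0.53 ± 0.37, -0.07 ± 0.84, 0.20 ± 0.43 and 0.28 ± 0.48. Gcs-1, sod-3 and vit-2 had changes of 0.11 ± 0.17, 0.36 ± 0.63 and -0.18 ± 0.21.

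With the replicate block, 5 genes fell with HgCl2 and 0 rose, with 1941 at an unadjusted p under 0.05. They were grd-7 (adjusted p = 0.0365), F36H1.12 (0.0365), the kinase gene kin-30 (-1.42, 0.0483), the insulin-like peptide gene ins-6 (-1.18, 0.0483) and K04D7.6 (-0.92, 0.0483), of which those other than grd-7 were chosen after their values were seen. No size is given for grd-7 and F36H1.12, which were not well above background on any HgCl2 array. The blocked count was 1 without Water 2, and 0 without HgCl2 2, Water 3, HgCl2 5 or Water 5. On simulated data 76% of genes changed by 2 (log2) and 26% of genes changed by 1 were recovered in this comparison without the block.

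None of the members of any list described for HgCl2 passed (0 by limma, also adjusted over the list alone). The median of 20 genes of the endoplasmic reticulum unfolded protein response was 0.18, with 19 of 20 above 0 (adjusted p = 4.28e-06, and 0.323 with an estimated correlation), sel-1 at 0.39 ± 0.17 and hsp-3 at 0.35 ± 0.16. The SKN-1 targets and glutathione S-transferases had medians of 0.01 and 0.02 (adjusted p = 0.619 and 0.863), which normexp left at -0.03 and 0.02. The mean of the latter was -0.06. Without HgCl2 2 these lists passed (medians 0.24 and 0.09, adjusted p = 0.0191 and 0.0484). The metallothionein and cadmium-responsive list had a median of 0.04 (adjusted p = 0.318) and the heat shock proteins one of -0.07 (adjusted p = 0.351, 0.0153 with normexp and 0.0118 without HgCl2 2). The innate immune effectors had a median of -0.18 (adjusted p = 0.251, 0.000832 with normexp, 0.0139 without Water 2 and 0.0136 without HgCl2 3). The intracellular pathogen response had a median of -0.36 (adjusted p = 0.0128, 0.905 with an estimated correlation and 0.0699 with the block). It was lost without HgCl2 2 (0.774), Water 3 (0.0511) or Water 4 (0.289). The germline and oocyte markers had a median of 0.19 (adjusted p = 0.0128, 0.905 with an estimated correlation, 0.323 with normexp, 0.0543 with quantile normalisation, 0.222 without HgCl2 2, 0.0953 without Water 2 and 0.188 without Water 3), and by number 1.198, 0.26 and -0.44. The sperm markers had a median of 0.22 (adjusted p = 0.00167, 0.905 with an estimated correlation, 0.231 without HgCl2 2 and 0.781 without Water 4), which was -0.02 with the block (adjusted p = 0.763). Without HgCl2 2 the medians of the intracellular pathogen response, the germline markers and the sperm markers were -0.05, -0.21 and 0.07. That of the germline markers was 0.08 without Water 3, 0.35 without Water 4, 0.41 without HgCl2 3 and 0.45 without HgCl2 5. That of the sperm markers was -0.02 without Water 4, 0.35 without HgCl2 5 and 0.53 without Water 2. In all, 11 of 35 lists passed with the preset correlation and 0 with an estimated one, where camera gave 4 lists an unadjusted p under 0.05.

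Methylmercury chloride against water asks which genes respond to organic mercury. Of all genes tested, 4.30% did not overlap between these groups in either direction, against 5.71% by chance. F07C4.6, on chromosome V at 7626850 to 7627783 (WBcel235, protein-coding), fell by 2.48 ± 0.28, or 5.60-fold (adjusted p = 0.00738), with all 3 meHgCl arrays below all 4 water arrays, as the naming rule required. It was the 1 gene that passed, with 501 genes (3.11%) at an unadjusted p under 0.05, below the 5% expected without any change. With normexp its change was -1.06 (adjusted p = 1), and its call was lost without meHgCl 2 (adjusted p = 0.068) or meHgCl 3 (0.090) and in a fit of the 2 groups alone (0.45). Mtl-1 and mtl-2 had changes of -0.79 ± 0.55 and -0.85 ± 0.23, cdr-1 and numr-1 of -0.52 ± 0.19 and -0.50 ± 0.34. Hsp-16.2, hsp-70, hsp-4 and hsp-6 had changes of -0.59 ± 0.37, -0.64 ± 0.84, 0.35 ± 0.43 and 0.20 ± 0.48. Gcs-1, sod-3 and vit-2 had changes of 0.36 ± 0.17, -0.13 ± 0.63 and -0.27 ± 0.21. With array weights mtl-2, cdr-1, gcs-1, uggt-1, spp-21 and spp-23 passed (adjusted p = 0.0088, 0.016, 0.027, 0.033, 0.012 and 0.029).

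With the replicate block, 2 genes rose and 54 fell with meHgCl, with 2860 at an unadjusted p under 0.05. Those that fell included the metallothionein gene mtl-2 (-0.86, adjusted p = 0.0490). Genes outside the naming rule, chosen after their values were seen, were gba-4 (-1.95, 0.0014) and the TGF-beta ligand gene daf-7 (-1.19, 0.0490), the lipase gene lipl-2 (-1.25, 0.00565) and ins-6 (-1.26, 0.0108). Gst-19 (-1.67 ± 0.31 without the block), spp-21 (-1.38 ± 0.41) and clec-169 (-1.99 ± 0.46) also passed with it (adjusted p = 0.00565, 0.00565 and 0.0018). The P450 gene cyp-33B1 (0.90, 0.0381) and ugt-31 (0.77, 0.0490) rose. The blocked count was 13 without Water 2, 22 without meHgCl 2, 4 without Water 3, 134 without meHgCl 3 and 14 without meHgCl 5.

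In the lists described for meHgCl, no member passed over all genes (0 by limma). The 20 unfolded protein response genes had a median of 0.17, with 18 above 0 (adjusted p = 0.000118, and 0.684 with an estimated correlation), uggt-1 at 0.40 ± 0.19 and hsp-3 at 0.27 ± 0.16. The proteasome subunits had a median of 0.15 (adjusted p = 0.000118, 0.689 with an estimated correlation, and 0.0706 without meHgCl 3), with rpn-1 at 0.53 ± 0.27 and rpn-11 at 0.31 ± 0.18. Of the metallothioneins and cadmium-responsive genes 1 fell adjusted over the list alone, and 1 fell with the block. Their median was -0.12 (adjusted p = 0.0326, 0.684 with an estimated correlation, 0.159 without Water 2 at a median of 0.02, 0.294 without meHgCl 2, 0.0688 without Water 5 and 0.0643 with the slide as a fixed block). The innate immune effectors had a median of -0.35 (adjusted p = 9.25e-07, 0.689 with an estimated correlation and 0.109 without meHgCl 2), and 3 fell with the block. The smallest p among them were those of spp-23 (-0.98 ± 0.29) and spp-21. The C-type lectins had a median of -0.20 (adjusted p = 0.00709, 0.684 with an estimated correlation), of which 3 fell adjusted over the list alone and 2 with the block. That call was lost without meHgCl 2 (0.0909), Water 4 (0.0853) or Water 5 (0.0846), and with no filter on dim probes (0.104, at a median of -0.14). Clec-168, at -1.19 ± 0.25, and clec-169 had the smallest p. Left-out arrays moved the medians of called lists. That of the proteasome subunits was 0.10 without Water 2 and that of the innate immune effectors -0.15 without meHgCl 2. That of the metallothionein list was -0.21 without meHgCl 3, -0.48 without Water 4 and -0.20 without Water 5.

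The intracellular pathogen response had a median of -0.36 with meHgCl (adjusted p = 0.00429, and 0.714 with an estimated correlation), lost without meHgCl 2 (0.113), meHgCl 3 (0.141) or Water 4 (0.198). The glutathione S-transferases had a median of -0.16 (adjusted p = 0.0677, and 0.0274 with the block), with 1 member, gst-19, that fell adjusted over the list alone, and with the block. They passed with normexp (adjusted p = 0.0229), with the slide as a fixed block (0.00430) and without meHgCl 3 (0.00254). The SKN-1 targets had a median of -0.05 (adjusted p = 0.643), with gcs-1 and dhs-8 (-0.57 ± 0.24) at the smallest p. The heat shock proteins had a median of -0.24 (adjusted p = 0.167, and 0.0315 without Water 3). The germline and oocyte markers had a median of 0.41 (adjusted p = 7.10e-05, 0.689 with an estimated correlation and 0.235 without meHgCl 2), and by number 1.28, 0.34 and 0.03. The sperm markers had a median of 0.06 (adjusted p = 0.206), which was -0.17 with the block (adjusted p = 0.187). They passed without Water 2 (0.38, adjusted p = 1.09e-07) or meHgCl 5 (0.31, adjusted p = 4.55e-05), and with the slide as a fixed block (0.25, adjusted p = 0.00218). The median of the intracellular pathogen response was -0.21 without meHgCl 3 and -0.60 without meHgCl 5, and that of the germline markers 0.10 without meHgCl 2 and 0.65 without meHgCl 3. In all, 11 of 35 lists passed with the preset correlation and 0 with an estimated one, where camera gave 1 list an unadjusted p under 0.05.

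**Figure D3:**
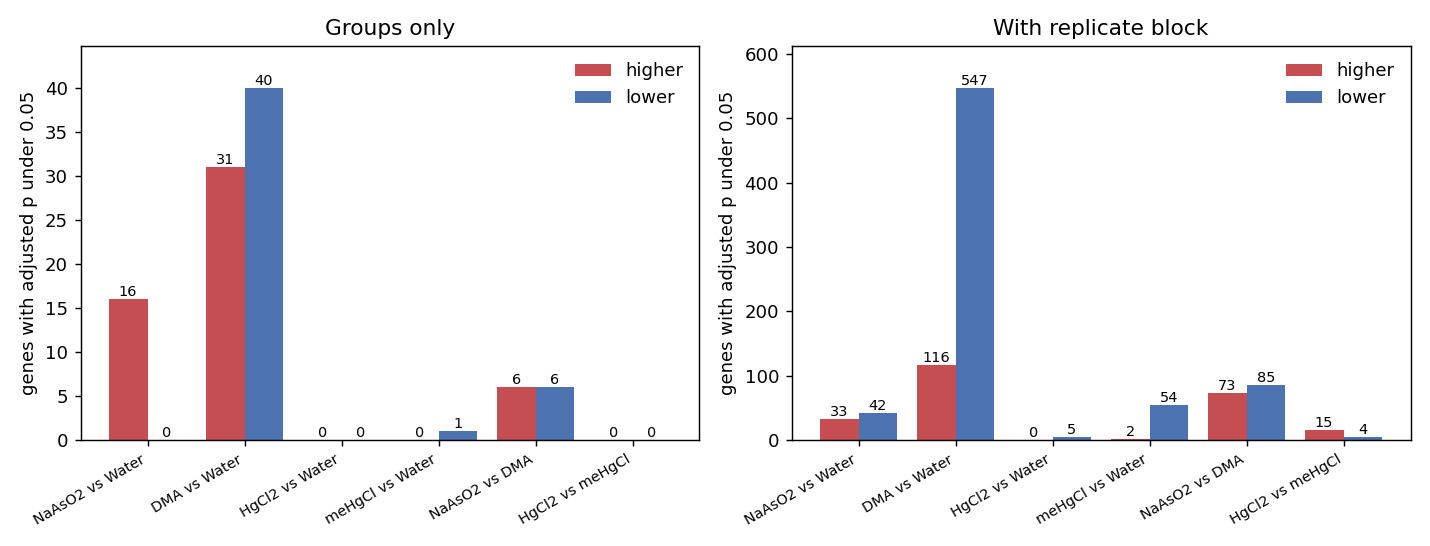
Number of genes past an adjusted p of 0.05 in each comparison, higher and lower, with groups only and with the replicate block, as bars from 0 with a separate vertical scale per panel. The block raised the count from 16 to 75 for NaAsO2, from 71 to 663 for DMA, from 0 to 5 for HgCl2 and from 1 to 56 for meHgCl.

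The direct comparison of NaAsO2 with DMA asks where the forms of arsenic differed, at 10 against 200 µg/ml. Levels of ugt-34 were at least 51.4-fold lower with NaAsO2, and C15B12.8 differed by -5.12 ± 0.31 (95% interval -5.78 to -4.45, adjusted p = 1.9e-06, n = 3 and 3). Cdr-1 differed by -2.26 ± 0.20 (-2.69 to -1.82, adjusted p = 0.000128) and cyp-35D1 by -2.41 ± 0.26 (-2.97 to -1.84, adjusted p = 0.00103). The gene gst-37 was at least 4.75-fold lower (adjusted p = 0.0019), and the histone gene his-11 differed by -1.23 ± 0.21 (adjusted p = 0.0484). Higher with NaAsO2 were dod-24 (1.68 ± 0.21, interval 1.25 to 2.12, adjusted p = 0.0025), F55G11.2 (1.85 ± 0.30, adjusted p = 0.0422), F55G11.6 (2.23 ± 0.35), clec-58 (2.15 ± 0.36), Y38E10A.9 (2.12) and C17H12.6 (2.00).

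In all, 12 genes differed between the forms of arsenic, 6 in each direction, and with the block 158 differed (73 higher, 85 lower). Without the block 937 genes (5.82%, against 5% expected without any change) had an unadjusted p under 0.05, and with it 3079 did. Without DMA 3, DMA 5, NaAsO2 3 or NaAsO2 5 the count was 6, and without NaAsO2 2 it was 7. Without NaAsO2 3, F55G11.2, F55G11.6, clec-58, Y38E10A.9, C17H12.6 and his-11 did not pass (adjusted p = 0.28, 0.27, 0.28, 0.13, 0.13 and 0.28). The same held without DMA 3, NaAsO2 5 or DMA 5 (adjusted p from 0.082 for C17H12.6 to 0.31 for clec-58). Without NaAsO2 2 those other than F55G11.6 were lost (up to 0.22 for his-11), and without DMA 2 those other than C17H12.6 (up to 0.14 for his-11). With normexp the differences of F55G11.6 (1.41), clec-58 (1.41), C17H12.6 (1.02), gst-37, cyp-35D1 (-1.46) and his-11 (-1.16) did not pass (adjusted p = 0.25, 0.29, 0.58, 0.58, 0.074 and 0.12). The call of F55G11.2 was lost with quantile normalisation (adjusted p = 0.053) and median scaling (0.065), as was that of clec-58 (0.059 and 0.055). With no filter on dim probes F55G11.2, clec-58 and his-11 did not pass (0.060, 0.069 and 0.076), with the slide as a fixed block F55G11.2 and Y38E10A.9 (0.064 and 0.053), and with robust moderation with a trend his-11 (0.053). In a fit of the 2 groups alone only ugt-34, C15B12.8 and Y38E10A.9 passed, and the others had adjusted p from 0.087 (clec-58) to 0.43 (F55G11.2). The blocked count was 58 without NaAsO2 2, 41 without NaAsO2 3, 36 without DMA 3, 63 without NaAsO2 5 and 49 without DMA 5.

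Of the genes that rose with either form of arsenic, 12 rose with both: gst-12, gst-16, gst-25, gst-30, nspa-1, nspa-5, nspa-8, clec-2, clec-3, F55G11.2, F01D5.3 and asp-14. No gene fell with both (0 by limma). With the block, 29 genes rose with both and 33 fell with both. Independent lists of these sizes would share 0.0308 rises without the block, and 0.238 rises and 1.43 falls with it, which does not allow for the shared water arrays. Without the block and with a different 2 of the water arrays for each form, 5 to 7 genes rose with both over the 6 ways to split them, and gst-12, gst-16, gst-25, gst-30 and nspa-8 were among them each time. Of the 12 genes, F55G11.2 was the only one called different between the forms. Among the others the 95% intervals of the difference excluded 0 for gst-12 (-1.03 to -0.19, adjusted p = 0.719) and, in the other direction, for clec-2 (0.03 to 1.81, adjusted p = 0.855). The rest included 0, such as -1.04 to 0.02 for gst-30, -0.42 to 1.72 for nspa-8 and -0.35 to 0.37 for asp-14, which do not show equal responses. The difference of nit-1 was 0.72 (0.14 to 1.31, adjusted p = 0.769).

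As lists, the metallothioneins and cadmium-responsive genes were lower with NaAsO2 than with DMA (median -0.34, adjusted p = 0.000485, and 0.277 with an estimated correlation), with 1 of 9, cdr-1, past the threshold, also adjusted over the list alone. The glutathione S-transferases had a median of -0.23 (adjusted p = 5.03e-06, and 0.898 with an estimated correlation), with 1 member lower, and 3 with the block. The UDP-glucuronosyltransferases had one of -0.18 (adjusted p = 0.000425, and 0.898 with an estimated correlation), with 1 member lower, 2 adjusted over the list alone and 5 with the block. The SKN-1 targets had one of -0.24 (adjusted p = 0.00318, 0.898 with an estimated correlation and 0.189 with normexp), with 0 members called by limma over all genes, 1 lower adjusted over the list alone and 2 with the block. That call was lost without NaAsO2 2 (0.106) or DMA 3 (0.10). The cytochromes P450 had one of -0.23 (adjusted p = 0.0333, and 0.898 with an estimated correlation), with 1 member lower, 1 higher and 3 lower adjusted over the list alone, and 1 higher and 7 lower with the block. It was lost with normexp (0.0521), median scaling (0.0963) and without NaAsO2 2 (0.75, at a median of 0.02), DMA 3 (0.459) or DMA 5 (0.188). The C-type lectins had a median of 0.27 (adjusted p = 3.29e-06, and 0.111 with an estimated correlation), which was -0.26 with normexp (adjusted p = 0.299), with 1 higher, 6 adjusted over the list alone, and 13 higher and 3 lower with the block. Left-out arrays moved these medians. Without NaAsO2 2 those of the metallothionein list, the glutathione S-transferases and the SKN-1 targets were -0.12, -0.14 and -0.13, and without DMA 2 they were -0.53, -0.48 and -0.49. Without DMA 3 the last 2 were -0.13 and -0.09, and without NaAsO2 3 that of the SKN-1 targets was -0.37. That of the cytochromes P450 was -0.51 without DMA 2, -0.35 without NaAsO2 3, -0.02 without DMA 3, -0.36 without NaAsO2 5 and -0.10 without DMA 5. That of the UDP-glucuronosyltransferases was -0.47 without DMA 2, -0.37 without NaAsO2 5 and -0.11 without DMA 5. In all, 14 of 35 lists passed with the preset correlation and 0 with an estimated one, where camera gave 2 lists an unadjusted p under 0.05.

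HgCl2 against meHgCl asks where the forms of mercury differed, at 2 against 0.5 µg/ml. No gene passed (0 by limma). At an unadjusted p under 0.05 there were 202 genes (1.25%), below the 5% expected without any change, and 948 with the replicate block. The smallest p-values were those of F07C4.6 (2.00 ± 0.30, 95% interval 1.34 to 2.65, adjusted p = 0.196), gst-19 (2.00 ± 0.33, adjusted p = 0.232), grd-7 (with a signal too dim for a size or a direction) and mtl-2 (1.09 ± 0.25). All of these passed with the block (adjusted p = 0.0020, 0.0020, 0.0322 and 0.0261), where 19 genes differed, 15 higher and 4 lower with HgCl2. F07C4.6 and gst-19 passed with the slide as a fixed block (0.0062 and 0.039) and as a random block (0.0079 and 0.039), and with array weights these and mtl-2 passed (0.0056, 0.0013 and 0.0066), as did sqrd-1 (0.022). The blocked count was 7 without HgCl2 2, 11 without meHgCl 2, 9 without HgCl2 3 or HgCl2 5 and 8 without meHgCl 5. Mtl-2 lies on chromosome V at 14018270 to 14018673 and gst-19 (F37B1.8) on chromosome II at 13625545 to 13627145 (WBcel235).

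The metallothioneins and cadmium-responsive genes had a median difference of 0.34 between HgCl2 and meHgCl (adjusted p = 0.000110, and 0.150 with an estimated correlation), with 1 member higher adjusted over the list alone, and 1, mtl-2, with the block. Cdr-1 differed by 0.56 ± 0.20. The 14 genes of the HIF-1 and sulfide response had a median of 0.30 (adjusted p = 1.80e-06, and 0.0946 with an estimated correlation), with 1 higher adjusted over the list alone, the sulfide oxidation gene sqrd-1 at 0.66 ± 0.17 and rhy-1 at 0.70 ± 0.30. The innate immune effectors had a median of 0.17 (adjusted p = 1.39e-05, and 0.867 with an estimated correlation), with spp-21 at 1.17 ± 0.44 and spp-23 at 0.77 ± 0.31, and 1 higher with the block. That call was lost without meHgCl 2 (0.563) or HgCl2 3 (0.0582). Without meHgCl 2 the median of the metallothionein list was 0.10. That of the innate immune effectors was 0.01 without meHgCl 2, 0.04 without HgCl2 3, 0.08 without HgCl2 5, and 0.35 without HgCl2 2 or meHgCl 3. In all, 11 of 35 lists passed with the preset correlation and 0 with an estimated one, where camera gave 3 lists an unadjusted p under 0.05.

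Across 16055 genes, which are not independent replicates, the responses to NaAsO2 and DMA correlated at 0.42, and unchanged groups simulated against the same water arrays at 0.43. With water split into 2 and 2 arrays the correlation had a mean of 0.11 over 6 splits (-0.10 to 0.28), and the covariance was 0.0656 against 0.0601 simulated. With the block the covariance was 0.0713 against 0.0310 simulated, while the correlation of 0.43 was below the simulated 0.50. For HgCl2 and meHgCl the correlation was 0.62 against 0.43 simulated and a mean of 0.08 with water split (-0.09 to 0.24), and the covariance was 0.0559 against 0.0597. With the block these were 0.69 against 0.50 and 0.0731 against 0.0311. For the other pairs the correlations were 0.65 (NaAsO2 and meHgCl), 0.55 (DMA and HgCl2), 0.52 (NaAsO2 and HgCl2) and 0.44 (DMA and meHgCl), each against 0.43 simulated, and means of 0.16, 0.14, 0.05 and 0.09 with water split (0.08 to 0.29, -0.03 to 0.24, -0.09 to 0.26 and -0.13 to 0.22). In the same order the covariances were 0.0707, 0.0708, 0.0532 and 0.0598 against 0.0599, 0.0602, 0.0603 and 0.0596 simulated. With the block these pairs had correlations of 0.72, 0.51, 0.60 and 0.44 against 0.50 simulated, and covariances of 0.0984, 0.0660, 0.0710 and 0.0649 against 0.0310 to 0.0311. The blocked covariance was thus above the simulated one in all 6 pairs, also between arsenic and mercury, and so is not particular to forms of the same metal. The simulation gave every array independent noise of the same SD per gene. Water, however, had the largest median absolute residual with the block (0.154, against 0.0996 to 0.137). A deviating water array would raise the covariance in every pair, so the excess does not show a shared response. Without the block, the simulation treated the number effects as independent noise, while real arrays of the same number share them. Shared effects partly cancel in contrasts with water, so the unblocked simulated values may be too high. Water split into 2 and 2 arrays leaves these effects unbalanced, which can pull those correlations down. The unblocked values therefore do not show that shared responses are absent. Without DMA 2 the correlation of NaAsO2 and DMA was 0.05, without HgCl2 2 that of HgCl2 and meHgCl was 0.18, and that of NaAsO2 and HgCl2 was -0.04. The latter was 0.31 without NaAsO2 2. That of DMA and meHgCl was 0.16 without DMA 2 and 0.24 without meHgCl 3, and that of NaAsO2 and meHgCl was 0.12 without meHgCl 2 and 0.41 without NaAsO2 2.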

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

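Of the tests in this part, those on the slide, on germline markers, on the spread of the mercury groups and on splits that part every numbered pair were chosen only after the results were seen. The water array numbered 2 had a level of 3.744 for the heat shock gene hsp-70, far from the other water arrays at 0.99 to 1.43. It was the only gene of 52 in which a water array stood that far from the rest, where 2.6 would be expected by chance at 1 in 20. All 5 arrays numbered 2 were high in hsp-70 (2.388 to 3.744, against 0.138 to 1.826 on the others), so it is part of the pattern of these arrays described below. The 12 genes that differed between NaAsO2 and DMA were a difference between groups, tested by the direct contrast in limma. Among probes without a gene name, which the comparisons of genes do not use, 5 passed the threshold with NaAsO2 and 6 with DMA. Of these, 5 probes of the transcript TC205221 rose by 1.91 to 1.998 with NaAsO2 and 1.75 to 1.91 with DMA, and a probe of BJ132094 fell by 1.28 with DMA.

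Other splits of the arrays were compared with the real groups. Read as pairs, the replicate numbers leave only 8 splits (4 between forms) that part every pair. That is too few for a share under 0.05, so chance stays open in each comparison. At least as many genes came from 1 of 8 such splits for NaAsO2 (16 genes in the real split and 0 in the highest other), 1 of 8 for DMA (71 and 0), 8 of 8 for HgCl2 (0 and 0) and 2 of 8 for meHgCl (1 and 1). Between NaAsO2 and DMA it was 1 of 4 (12 and 0) and between HgCl2 and meHgCl 4 of 4 (0 and 0). Any split reaches a real count of 0, so for HgCl2 and between the mercury forms this outcome was fixed in advance. The remaining splits keep at least 1 pair together. Over all 35 splits the highest other count was 0 for NaAsO2, 3 for DMA, 6 for HgCl2 and 1 for meHgCl, so a split of the HgCl2 and water arrays that is not the treatment gave more genes than the treatment. For few genes with HgCl2, the ratio of the group's median gene SD to that of the DMA group was 1.005, and that of the median absolute residual with the block 0.95. For meHgCl these ratios were 1.107 and 1.305. The fit shares 1 variance per gene over all groups, so a gene without missing values has the same SE for each compound against water. These ratios therefore cannot decide why few genes passed with HgCl2 or meHgCl.

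The phase II targets of SKN-1 were higher with both forms of arsenic. With the slide as a block, the lower ratio of the list medians with and without it was 1.029, which argues against slide or scan differences as the cause. The 6 members that are no glutathione S-transferase (gcs-1, sdz-8, dhs-8, F20D6.11, ugt-13 and nit-1) had medians of 0.8292 with NaAsO2 and 1.06 with DMA, all above 0, which argues against signal shared between glutathione S-transferase probes as the whole cause. With an estimated correlation the list kept its call with DMA (adjusted p = 0.0290) and not with NaAsO2 (adjusted p = 0.0537). Whether SKN-1 itself acted stays open, since protein and activity were not measured.

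The arrays numbered 2 stood apart from the rest in every group. Of the 5, 4 lie on a slide that holds no other arrays. The array on another slide scored 71.48 on the first component, against -42.01 to 4.173 for its slide mates. The other arrays numbered 2 scored 18.29 (Water 2) and, for the treated ones, 55.81 to 70.25. A single array does not separate the number from the slide, so slide or scan differences stay open. Of the 5 arrays, 3 were brighter than every other array, of which the highest had a 75th percentile of 1714, so brightness stays open. Germline and oocyte markers were higher on them in 92.59% of members, which more germline RNA could give. Other lists were higher as well: DNA damage genes in 12 of 12 members, methionine cycle genes in 86.67% and heat shock proteins in 82.35%. Sperm markers, which are germline genes too, were higher in 87.18%. Whether germline RNA also raised these lists was not tested, so they do not argue against it. Neuron markers were higher in 6.25%, intracellular pathogen response genes in 8.824%, innate immune effectors in 11.59% and lysosomal lipases in 0 of 7, against 51.83% of all genes. The test of germline markers was chosen after the pattern was seen, age or preparation was not tested, and the cause stays open.

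Genes called with DMA lay near each other. There were 8 pairs at most 3 genes apart, against a mean of 0.930 and a maximum of 7 in 10000 random sets (permutation p = 1e-04, the smallest possible), so random placement did not give as many. All 8 pairs changed in the same direction, and 6 were of the same gene family, such as gst-12, gst-14 and gst-16 on chromosome II. Signal shared between probes of related genes was not tested and stays open.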

How the results depend on the processing

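Of the alternatives, leaving out the arrays numbered 2, testing all probes, leaving out arrays with the block, the block and left-out arrays for the overlaps, and split water for the genes shared by the arsenic forms were chosen after seeing the data. Of the log2 fold changes of named genes under another setting, 1716 kept direction and side of the threshold, 36 passed only there, 84 no longer passed and 24 turned direction. The block ended no gene's call. The causes of the changes below were not tested, except that fits of 2 groups alone and fits without an array hold fewer samples.

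Quantile normalisation, the authors' table and the filters kept every count of genes within 1.5 times. The authors' table is scaled nearly as the main values are, so its agreement was built in. The block gave 75 genes for NaAsO2, 663 for DMA, 5 for HgCl2, 56 for meHgCl, 158 between the arsenic forms and 19 between the mercury forms. Array weights gave 81, 1813, 26, 425, 2084 and 12 in the same order. The slide as a fixed block gave 189 for DMA, 1 for HgCl2, 8 for meHgCl, 19 and 5 between forms. The slide as a random block gave 28, 278 and 1 for NaAsO2, DMA and HgCl2, and 26 and 2 between forms. Without the arrays numbered 2 there were 25 for NaAsO2, 123 for DMA, 0 for meHgCl by limma, 20 and 1 between forms, and with the block as well 32, 239, 15, 164 and 11. All probes gave 28 for NaAsO2. Normexp, which changes the background step and the intensity used together, gave 35 for DMA, 0 for meHgCl and 7 between the arsenic forms, and fits of 2 groups alone gave 13, 0 and 3. With 1 array left out the counts ranged from 9 to 18 for NaAsO2, 16 to 187 for DMA, 0 to 1 for meHgCl and 6 to 10 between the arsenic forms.

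Single genes that turned direction with normexp were clec-168 with DMA (0.13), grd-7 with HgCl2 (0.11) and between the mercury forms (0.17), and mtl-1 with HgCl2 (0.0049). With median scaling these were vit-2 with DMA (0.081) and mtl-1 with HgCl2 (0.038), and with the mean of probes vit-2 with DMA (0.020). With the block they were hsp-70 with NaAsO2 (-0.022) and mtl-1 with HgCl2 (0.0065). With the slide as a fixed block they were hsp-70 (-0.073), hsp-4 (-0.066) and sod-3 (0.17) with NaAsO2 and mtl-1 with HgCl2 (0.0063), and as a random block hsp-4 (-0.011) and sod-3 (0.072) with NaAsO2. With array weights they were hsp-70 with NaAsO2 (-0.067), and mtl-1 (0.038), cdr-1 (-0.015) and hsp-4 (-0.033) with HgCl2. Without the arrays numbered 2 they were cdr-1 (-0.087, and -0.095 with the block) and sod-3 (0.30) with NaAsO2, hsp-4 with HgCl2 (-0.13) and sod-3 with meHgCl (0.18).

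With 1 array left out, changes with NaAsO2 ranged from -0.66 to 0.089 for mtl-1, -0.10 to 0.25 for cdr-1, -0.50 to 0.75 for hsp-70, -0.16 to 0.23 for hsp-4, -0.16 to 0.65 for hsp-6 and -0.41 to 0.50 for sod-3. With DMA the ranges were -0.12 to 0.58 for mtl-1, -0.40 to 0.073 for hsp-16.2, -0.83 to 0.42 for hsp-70, -0.062 to 0.62 for hsp-6 and -0.20 to 0.086 for vit-2. With HgCl2 they were -0.36 to 0.33 for mtl-1, -0.016 to 0.095 for cdr-1, -0.88 to 0.58 for hsp-70, -0.30 to 0.45 for hsp-4 and -0.11 to 0.55 for hsp-6. With meHgCl they were -1.25 to 0.0078 for hsp-70, -0.027 to 0.55 for hsp-4, -0.15 to 0.47 for hsp-6 and -0.45 to 0.39 for sod-3.

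Of 66 list calls over the 6 comparisons, 2 remained with an estimated correlation and 6 with fry. The median, or the direction camera gave, turned for the SKN-1 targets with HgCl2 under normexp (-0.034) and with meHgCl under the block (-0.16), the slide (-0.11) and fry (-0.051). It also turned for the glutathione S-transferases with HgCl2 under normexp (0.0194), the block (-0.056) and fry (0.0195), for the germline markers with DMA under normexp (0.053) and for the sperm markers with meHgCl under the block (-0.17). With 1 array left out, medians with HgCl2 ranged from -0.064 to 0.24 for the SKN-1 targets, -0.10 to 0.089 for the glutathione S-transferases, -0.23 to 0.052 for the innate immune effectors, -0.54 to -0.053 for the intracellular pathogen response, -0.20 to 0.081 for the heat shock proteins and -0.21 to 0.45 for the germline markers. With meHgCl they ranged from -0.16 to 0.16 for the SKN-1 targets, -0.30 to -0.015 for the glutathione S-transferases and -0.17 to 0.38 for the sperm markers. With DMA they ranged from -0.094 to 0.36 for the cytochromes P450, -0.21 to 0.080 for the heat shock proteins and -0.24 to 0.38 for the germline markers, and with NaAsO2 from -0.17 to -0.019 for the C-type lectins and -0.28 to 0.27 for the sperm markers.

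With water split into 2 and 2 arrays, the mean correlations of responses over 6 splits were 0.11 (NaAsO2 and DMA), 0.078 (HgCl2 and meHgCl), 0.054 (NaAsO2 and HgCl2), 0.088 (DMA and meHgCl), 0.16 (NaAsO2 and meHgCl) and 0.14 (DMA and HgCl2). With 1 array left out they ranged, in the same order, from 0.052 to 0.59, 0.18 to 0.75, -0.040 to 0.68, 0.16 to 0.61, 0.12 to 0.76 and 0.37 to 0.69. Signal over background limits the size of changes of dim genes such as ugt-34, gst-37 and grd-7, for which a group was not well above background.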

Other observations

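In this part, the tests of gene families were chosen only after the result was seen. They count genes as independent, while members of a family may move together or share signal, so their p-values may be too small. The F-box genes named fbxb, whose proteins carry a motif that links them to ubiquitin ligases, were 1 of 2 families that passed with DMA without the block. The other was gst, with 7 of 41 higher (adjusted p = 1.59e-10). Of 97 fbxb genes tested, 8 fell with DMA and 0 rose (Fisher's exact test among 156 families, adjusted p = 1.33e-08), and 41 fell with the replicate block. Other families that passed among the blocked falls were clec (23 of 166), sdz (8 of 27), fbxc (9 of 45), clc (6 of 24), nssp (9 of 76) and str (7 of 53), with adjusted p from 7.94e-07 (clec) to 0.0446 (str). The median change of the fbxb genes with DMA was -0.66, with 94 of 97 below 0, and by replicate number it was -1.05, -0.79 and -0.54. With normexp background correction the median was 0.00 and none fell. Normexp also changed the intensity used, and which of its changes moved the family was not tested. The family's median level in water was -3.55 against -0.88 for all genes, and 83 of the 97 were well above background on all 16 arrays. Left-out arrays gave 0 genes (DMA 2, DMA 3 or Water 5), 1 (Water 3), 2 (Water 2), 3 (Water 4) and 20 (DMA 5), while the family's median in these fits was -0.51 to -0.76, with 87 to 95 of 97 below 0. With NaAsO2, HgCl2 and meHgCl the family's median was -0.20, -0.33 and 0.01, with 80, 84 and 46 of 97 below 0, and none fell. Between NaAsO2 and DMA none of the 12 genes that differed was an fbxb gene, while with the replicate block 7 of the 97 were higher with NaAsO2 (Fisher's exact test, adjusted p = 2.13e-05). Clec passed there as well, with 13 of 166 higher (adjusted p = 7.32e-11), and cyp and ugt with 7 of 70 and 5 of 64 lower (adjusted p = 1.27e-05 and 0.0017). For the 8 genes that fell with DMA, which were chosen for that fall, the 95% intervals of NaAsO2 minus DMA without the block lay above 0, such as 0.41 to 1.38 for fbxb-62, with adjusted p from 0.48 to 0.77.

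Some genes called with DMA and outside the naming rule, chosen after their values were seen, have known roles. The lipid-binding protein gene lbp-8 rose by 2.85, gst-35 by 2.67 and wdr-23, which encodes an inhibitor of SKN-1, by 0.65, while the insulin-like peptide genes ins-2 and ins-7 fell by 1.13 and 0.89.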
